A study of Mus musculus with 10 samples.

How the data were processed

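RNA was sequenced from the medial habenula, a small epithalamic nucleus rich in cholinergic neurons and nicotinic receptors, of 10 wild-type mice. There was 1 library per mouse. Per the labels' protocols, 6 mice received nicotine ditartrate (4 mg/kg by intraperitoneal injection, 2 injections a day) for 14 days and saline from day 15. The 4 control mice received saline throughout, and tissue was taken on day 17, per the labels' protocols. The labels describe the material in different ways: the source label names cholinergic neurons sorted by flow cytometry, and the series record names brain tissue without a sort. RNA was extracted with TRIzol and libraries were prepared from 1 µg of total RNA with a VAHTS Universal V8 kit, per the labels' protocols. No batch, sex or litter is given in the labels.

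The deposited table held 56691 Ensembl genes with a read count column and an FPKM column for each library. The count columns were raw read counts per gene made by the authors, per the file headers, and their values were whole numbers. The FPKM columns were deposited as FPKM (fragments scaled to gene length and library total), per the file headers. They were proportional to the counts: over 1406 genes with at least 2000 counts in every library, the largest relative gap between count over FPKM and the library total was 0.00161. Per the submitters' processing notes, the tools were cutadapt 1.9.1, HISAT2 2.2.1 and HTSeq 0.6.1 with the mouse build mm39. The annotation release, the strand setting of the counting and the gene lengths were not given in the sources used here. Antisense and overlapping genes could therefore not be told apart by strand, and near-identical copies (Mt1 and Mt2, Hspa1a and Hspa1b, the alpha and beta globin genes) may share reads. Gene symbols were taken from GENCODE M21, which named 52073 of the 56691 identifiers. That release belongs to another build than mm39, so no coordinates are given.

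Library totals ran from 15023448 to 22026333 counts. Genes with a mean FPKM of at least 1 over the 10 libraries were tested, which kept 14928 genes and at least 99.0% of the counts of each library. The main comparison, nicotine withdrawal (n = 6) minus control (n = 4), used the quasi-likelihood test of edgeR 4.0.16 with TMM factors on the counts in R 4.3.3. It was 2-sided, with Benjamini-Hochberg adjustment over all genes, a threshold of 0.05 and no fold threshold. The design written beforehand had assumed that only FPKM were present and named limma on log2(FPKM + 1). Because counts were present, the count model replaced it, and limma 3.58.1 on log2(FPKM + 1) became an alternative. Levels are given as CPM (counts scaled to a common library total) with TMM factors, with the standard deviation (SD) over libraries, and log2 fold changes with their standard error (SE). Marker transcripts given for single libraries were chosen after the data were seen. PCR reads carry no molecular identifiers, so the counting precision is a lower bound on the error.

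The comparison, the thresholds, the 40 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 12 rising and 12 falling genes with the largest change among those past the threshold whose groups did not overlap, without predicted or clone-named genes. It also named Chat, Slc18a3, Slc5a7, Tac1, Tac2, Pou4f1, Chrna3, Chrna5, Chrnb4, Chrna4, Chrnb2 and Slc17a6, and from each list up to 4 measured members with the smallest unadjusted p. The lists covered markers of the ventral and the dorsal and lateral medial habenula, the lateral habenula, hippocampal and cortical, thalamic and GABAergic neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium and pericytes, meningeal fibroblasts, ependyma, choroid plexus, pineal gland and blood. They also covered acetylcholine handling, nicotinic receptors and their chaperones, muscarinic, glutamate, GABA and neuropeptide receptors, ion channels, vesicle release, cyclic AMP, immediate early, heat shock, unfolded protein, glucocorticoid, clock and interferon genes, energy metabolism, ribosome, proteasome and sex-linked genes. Lists with at least 3 measured genes (39 of 40, since no pineal list member passed the filter) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They were tested again with an estimated correlation and with fry. A list score was the mean log2 CPM of the list's genes in a library, with a prior count of 2. Group differences of scores were compared with exact 2-sided permutation tests over all 210 splits of the libraries, or 56 splits of 8 libraries.

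The edgeR and list tests were tested on simulated counts with 200 changed genes among 14928. With all 10 libraries they recovered 11.9%, 47.8% and 72.7% of genes changed 1.5-fold, 2-fold and 4-fold, with 4 false calls among 92. With 8 libraries, without control 2 and withdrawal 2, they recovered 62.7%, 83.6% and 97.0%, with 8 false calls among 170. Genes were simulated independently, with no difference in tissue content between libraries. In the real 10 libraries a split other than the real one gave 177 changed genes. The simulated recovery and false calls may therefore not hold for these data. In the simulated counts the list test recovered the 1 list that was moved and called none of the others. In the real libraries 51 of 100 splits gave as many lists as the real split. The simulation therefore does not show how often this test calls lists by chance in these data. Alternatives were other pseudocounts, filters, scalings, variance moderation, library weights, a replicate block, fold thresholds and leaving out each library, all fixed beforehand. DESeq2 1.42.0, limma on log2(FPKM + 1), the filterByExpr filter, and leaving out control 2 and withdrawal 2, whose habenula transcripts were near-absent, were added after the data were seen. No library was left out of the main comparison.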

Results

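The data were RNA-seq read counts from the medial habenula of 10 mice: 4 saline controls and 6 mice in nicotine withdrawal. The comparison asks which transcripts differ in the medial habenula during withdrawal from repeated nicotine. Total counts were 15023448, 22026333, 16483230 and 21014662 in controls 1 to 4. They were 16667113, 20276566, 19329207, 16864719, 20132024 and 17958045 in withdrawal 1 to 6. Between 24681 and 27067 genes had at least 1 count in a library, and mitochondrial genes took between 4.57% and 6.10% of the counts.

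Medial habenula transcripts were abundant in 8 libraries and near-absent in 2, control 2 and withdrawal 2. Chat, the enzyme that makes acetylcholine, lay between 26.6 and 40.7 CPM in the other 8 libraries, but at 0.165 CPM (3 counts) in control 2 and 0.2004 CPM (4 counts) in withdrawal 2. Chrnb4, a nicotinic receptor subunit concentrated in this nucleus, lay between 83.4 and 134 CPM in the 8 libraries, and at 0.330 and 1.95 CPM in these 2. Pou4f1, a habenula transcription factor, lay between 95.05 and 157 CPM, and at 0.275 and 1.15 CPM. Control 2 instead carried high levels of Neurod6 (345 CPM) and Wfs1 (646 CPM), which mark hippocampal and cortical excitatory neurons. Wfs1 was 89.4 CPM in withdrawal 2, against 34.3 to 45.1 CPM in the other 8. Gad1, which marks GABAergic neurons, was high in both, at 406 CPM in control 2 and 516 CPM in withdrawal 2. It lay between 34.1 and 181 CPM in the other 8. Transcripts of non-neuronal cells were present in all 10 libraries. Mbp, a myelin protein, lay between 2420 and 6109 CPM, and Gfap, an astrocyte filament, between 227 and 646 CPM. Ttr, made by choroid plexus, lay between 26.9 and 11879 CPM. The first principal component, with 57.9% of the variance, set control 2 apart. The median correlation with the other libraries of its group was 0.893 for control 2 and 0.939 for withdrawal 2.

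**Figure D1:**
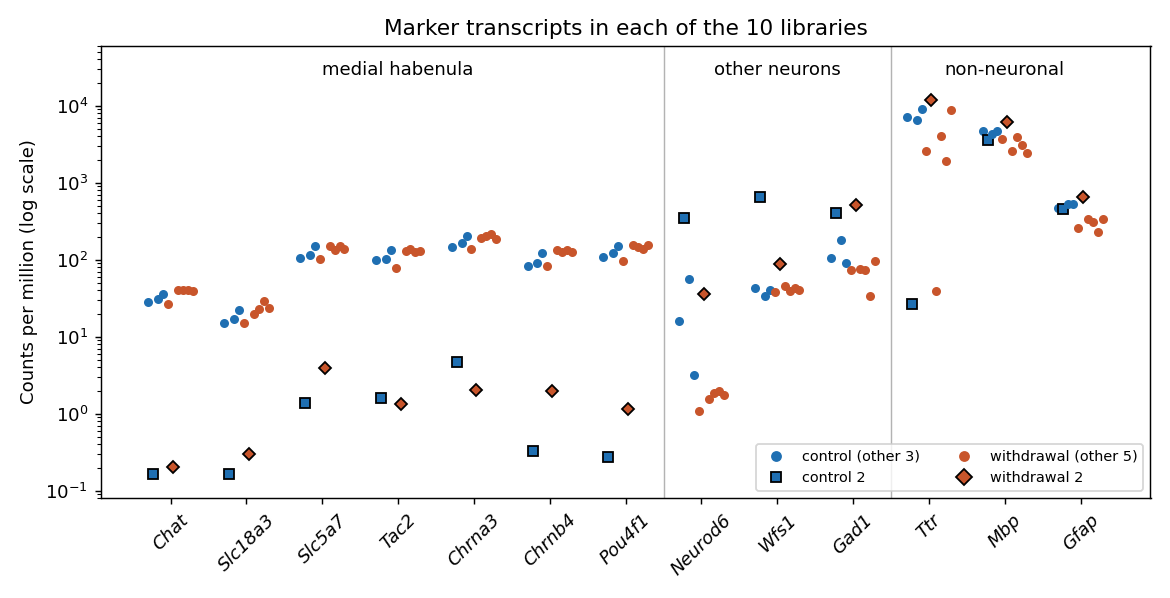
Levels in CPM (log scale) of medial habenula, other neuronal and non-neuronal marker transcripts in each of the 10 libraries, 1 point per library, with control 2 and withdrawal 2 as outlined squares and diamonds. Chat lies between 26.6 and 40.7 CPM in 8 libraries and at 0.165 and 0.2004 CPM in the outlined 2, while Mbp lies between 2420 and 6109 CPM in all 10.

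In withdrawal, 26 genes were lower than in controls, among them Plin4, Hif3a, Mfsd2a, Mt2 and the glucocorticoid-responsive gene Fkbp5, and 5 genes were higher, among them Fabp7. Plin4 (ENSMUSG00000002831), a lipid droplet coat protein, fell from 64.0 ± 22.04 CPM (SD, n = 4) in controls to 8.49 ± 2.30 CPM (SD, n = 6) in withdrawal, a log2 change of -2.91 (SE 0.264, edgeR adjusted p = 0.00461). Hif3a (ENSMUSG00000004328), a member of the hypoxia-inducible factor family, fell from 24.5 ± 3.09 to 5.63 ± 1.73 CPM (log2 change -2.12, SE 0.218, edgeR adjusted p = 0.00755). Mfsd2a (ENSMUSG00000028655), a lysophospholipid transporter of the blood-brain barrier, fell from 25.9 ± 4.38 to 11.4 ± 1.05 CPM. Mt2 (ENSMUSG00000031762), a metallothionein, fell from 51.1 ± 1.88 to 23.6 ± 3.17 CPM. Their log2 changes were -1.19 (SE 0.118, edgeR adjusted p = 0.00715) and -1.11 (SE 0.1003, edgeR adjusted p = 0.00461). Fabp7, a brain fatty acid-binding protein of astrocytes and radial glia, rose from 14.9 ± 4.04 to 59.3 ± 17.2 CPM (log2 change 1.99, SE 0.286, edgeR adjusted p = 0.0357).

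In all, 31 of 14928 genes changed, 5 higher and 26 lower, and 2306 had an unadjusted p under 0.05 (923 higher and 1383 lower). In each of the 31, all 6 withdrawal libraries lay on one side of all 4 controls, which held for 494 tested genes (3.31%), against 0.952% by chance. The other falling genes among the 12 largest were Fkbp5, a co-chaperone of the glucocorticoid receptor, with a log2 change of -1.69, Arrdc2 (-1.47), the sulfotransferase Sult1a1 (-1.33), the receptor partner Ramp2 (-1.31), the clock gene Per2 (-1.28), Plekhf1 (-1.26), the phagocytic receptor Mertk (-1.22) and the mTOR inhibitor Ddit4 (-1.03). Their edgeR adjusted p lay between 0.0165 (Plekhf1) and 0.0458 (Per2). The other rising genes were the transcription factor Rfx4 (0.80), the membrane metalloprotease Mmp14 (0.71), the mitochondrial nucleotide kinase Cmpk2 (0.53) and, outside the rule and named after its values were seen, the predicted gene Gm38394 (1.09). Plin4, Hif3a, Mfsd2a and Mt2 were called whichever library was left out, while Fkbp5 was called in 1 of the 10 settings and Fabp7 in 2. The number of genes changed in withdrawal was 10, 34, 4 and 7 without control 1, 2, 3 and 4. It was 4, 893, 4, 4, 4 and 5 without withdrawal 1 to 6. All 31 kept their direction in these 10 settings, and DESeq2 called 381 genes, these 31 among them. By contrast, limma on log2(FPKM + 1), the test named beforehand, called 12 genes, with 10 of the 31 among them. With a replicate block edgeR called 0.

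Glucocorticoid-responsive genes fell as a group. All 13 measured members had lower means in withdrawal, with a median log2 change of -1.004 (camera adjusted p = 8.48e-29). With an estimated correlation the adjusted p was 0.0113, and with fry it was 2.89e-04. Of the 13, 7 fell when adjusted over all genes and 12 when adjusted over the list alone. Mt2, Ddit4, Sult1a1 and Mt1 had the smallest unadjusted p, and Mt1 fell from 90.9 ± 3.20 to 55.6 ± 7.27 CPM (log2 change -0.71, edgeR adjusted p = 0.0296). Chosen after their values were seen, Zbtb16, a transcription factor induced by glucocorticoids, had 80.2 ± 39.5 and 13.1 ± 8.34 CPM (log2 change -2.61, edgeR adjusted p = 0.0578). Sgk1, a kinase named for serum and glucocorticoid regulation and chosen the same way, had 232 ± 72.2 and 75.2 ± 30.8 CPM (log2 change -1.62, edgeR adjusted p = 0.0884). The mean list score was 5.83 ± 0.0978 in controls and 4.68 ± 0.258 in withdrawal (SD, n = 4 and 6). It was lower in 6 of 6 withdrawal libraries than in any control (exact permutation p = 0.00476, the smallest that 210 splits can give, and 0.0929 adjusted over 39 lists). The heat shock score gave the same values, and none of the 39 lists passed this test after adjustment. The hippocampal and cortical marker score was also higher in controls, 5.59 ± 1.22 against 3.78 ± 0.75. Without control 4, the adjusted p with an estimated correlation was 0.0505.

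**Figure D2:**
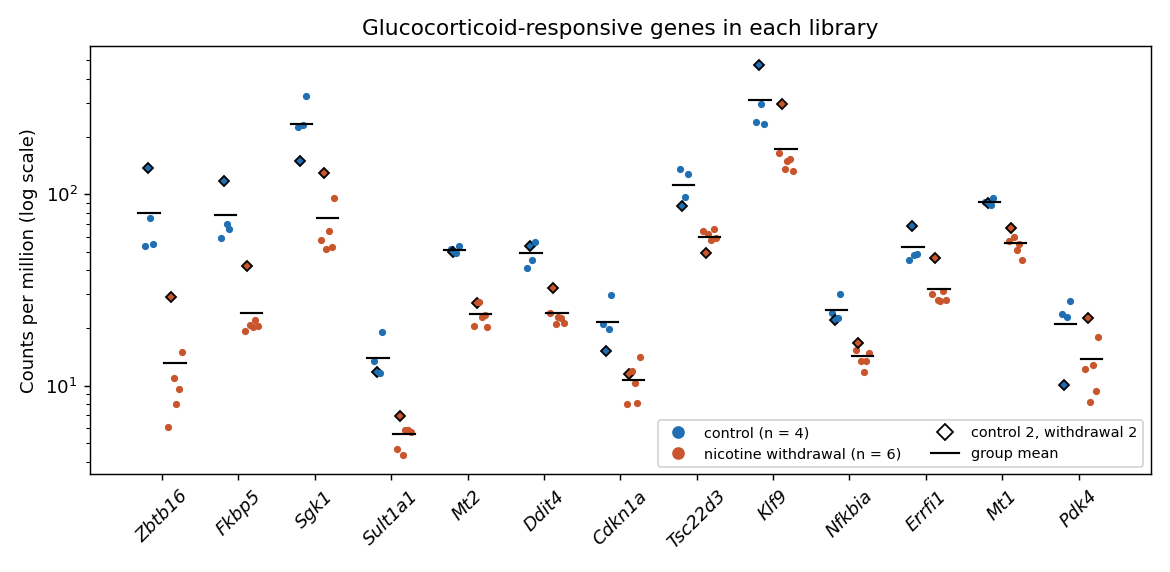
Levels in CPM (log scale) of the 13 measured glucocorticoid-responsive genes in each library of controls (n = 4, blue) and nicotine withdrawal (n = 6, orange), with group means as bars and control 2 and withdrawal 2 as outlined diamonds. Mean levels were lower in withdrawal for all 13 genes, such as Fkbp5 at 24.1 CPM against 78.0 CPM.

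Medial habenula and cholinergic transcripts were not called as changed in the main comparison. Over all 10 libraries, Chat had a log2 change of 0.40 (SE 1.07), the acetylcholine transporter Slc18a3 0.45 (SE 1.00), the choline transporter Slc5a7 0.27 (SE 0.993), the tachykinins Tac1 and Tac2 0.21 and 0.25, and Pou4f1 0.27 (SE 1.16). Their edgeR adjusted p lay between 0.846 and 0.924. The nicotinic subunits Chrna3, Chrnb4, Chrna4 and Chrnb2 had log2 changes of 0.25, 0.44, 0.70 and 0.33 (edgeR adjusted p from 0.303 to 0.920), and the glutamate transporter Slc17a6 0.97 (edgeR adjusted p = 0.582). Chrna5 had a log2 change of -1.59 (SE 0.726, edgeR adjusted p = 0.326), with 18.1 CPM in control 2 and between 0.701 and 2.95 CPM in the other 9 libraries. Without control 2, Chrna5 had a log2 change of 0.073, Chat -0.021, Chrna3 -0.16, Pou4f1 -0.15, Slc5a7 -0.14, Tac1 -0.12 and Tac2 -0.16, with withdrawal 2, which lacked most habenula transcripts, still included. Without both libraries the log2 changes of these 7 genes were 0.24, 0.24, 0.095, 0.11, 0.11, 0.13 and 0.098, and none passed. Chrna4 and Slc17a6 did pass in those 8 libraries, with log2 changes of 0.65 and 0.78 (edgeR adjusted p = 0.0133 and 0.0213). The ventral medial habenula, acetylcholine and nicotinic receptor lists had camera adjusted p of 0.525, 0.377 and 0.686.

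Interferon-response genes were higher in 15 of 16 measured members, with a median log2 change of 0.69 (camera adjusted p = 1.26e-07, and 0.638 with an estimated correlation). The interferon score did not pass the exact permutation test after adjustment (p = 0.0381, adjusted p = 0.186). None of the 16 passed in edgeR when adjusted over all genes and 7 rose when adjusted over the list alone. Irf7, a regulator of interferon genes, had 2.93 ± 0.919 and 6.80 ± 1.96 CPM (log2 change 1.21), and Ifit1, an interferon-induced RNA-binding protein, 4.78 ± 1.16 and 10.2 ± 4.00 CPM (log2 change 1.09). Blood cell markers were also higher in 5 of 5 members, with a median of 1.91 (camera adjusted p = 0.00496, and 0.638 with an estimated correlation). In edgeR 0 members passed over all genes and 5 adjusted over the list alone. The blood score did not pass the exact permutation test (p = 0.0714, adjusted p = 0.214). Withdrawal 2 held the highest Hbb-bs, an adult beta globin, at 349 CPM, against 16.4 to 96.8 CPM in the other 9 libraries. The mean log2 CPM of the interferon list was highest in withdrawal 2, 6 and 4 (4.62, 4.29 and 4.16), which also held the highest blood marker scores (5.99, 4.03 and 3.77), and was lower in withdrawal 3 and 5 (3.45 in both) than in control 1 (3.54). Without both control 2 and withdrawal 2, the interferon list had a median of 0.39 (camera adjusted p = 0.00341; adjusted p = 0.667 with an estimated correlation) and the blood list an adjusted p of 0.0751.

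Hippocampal and cortical neuron markers were lower in withdrawal, with 8 of 8 members lower and a median of -1.87 (camera adjusted p = 4.13e-05; adjusted p = 0.638 with an estimated correlation). None of these passed in edgeR over all genes and 6 did when adjusted over the list alone. The transcription factor Neurod2 had 120 ± 102 CPM in controls and 21.1 ± 27.8 CPM in withdrawal (log2 change -2.51), and Neurod6 had 105 ± 162 and 7.34 ± 14.0 CPM (log2 change -3.83). Without control 2, Neurod6 was still higher in the other controls, at 15.9, 56.7 and 3.22 CPM in controls 1, 3 and 4, against 1.07 to 1.97 CPM in the 5 withdrawal libraries other than withdrawal 2 (35.8 CPM). Thalamic neuron markers were higher in 7 of 7 members, with a median of 0.92 (camera adjusted p = 0.0121, and 0.638 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The thalamic score did not pass the exact permutation test (p = 0.129, adjusted p = 0.313). Rora and Ramp3 had log2 changes of 0.73 and 1.31. The thalamic list missed the threshold in limma on log2(FPKM + 1) (adjusted p = 0.0805).

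Immediate early genes, which follow neuronal activity, were lower in 13 of 16 members, with a median of -0.81 (camera adjusted p = 0.00496, and 0.638 with an estimated correlation). The immediate early score did not pass the exact permutation test (p = 0.0524, adjusted p = 0.186). No member passed in edgeR over all genes or adjusted over the list alone. Arc had 74.7 ± 85.8 and 24.4 ± 15.6 CPM (log2 change -1.61) and Fosl2 24.0 ± 10.8 and 9.56 ± 6.73 CPM (log2 change -1.32). Arc reached 202 CPM in control 2, the library with the most Neurod6, and without control 2 the list's median was -0.31 (adjusted p = 0.0882). The circadian clock list was lower with a median of -0.14 (camera adjusted p = 0.00496; adjusted p = 0.638 with an estimated correlation), with 11 of 16 members lower, 2 past the threshold over all genes and 3 adjusted over the list alone. Per2 and Per1, repressors of the clock that also respond to hormones, fell by 1.28 and 0.61 on the log2 scale, and Per3 had a log2 change of -0.44 (edgeR adjusted p = 0.136). Without control 2 the clock list's median was 0.0015 (adjusted p = 0.353).

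Heat shock genes were lower with a median of -0.12 (camera adjusted p = 0.0319; adjusted p = 0.638 with an estimated correlation), with 8 of 10 members lower, 0 past the threshold over all genes and 4 adjusted over the list alone. Hspa1b, an inducible chaperone, had 14.9 ± 9.38 and 4.44 ± 0.984 CPM (log2 change -1.74), and Hspa1a, a near-identical copy that may share its reads, had 9.06 ± 4.16 and 4.51 ± 0.533 CPM (log2 change -1.004). Unfolded protein response genes were lower in 10 of 11 members with a median of -0.18 (camera adjusted p = 0.0262; adjusted p = 0.638 with an estimated correlation). Ependymal markers were higher in 7 of 7 with a median of 0.44 (camera adjusted p = 0.0258; adjusted p = 0.752 with an estimated correlation). Ribosomal protein genes were higher in 36 of 38 with a median of 0.10 (camera adjusted p = 0.00148; adjusted p = 0.638 with an estimated correlation). No member of these 3 lists passed in edgeR over all genes or adjusted over the list alone. Sdf2l1, an endoplasmic reticulum protein, had a log2 change of -0.71, the ciliary gene Ccdc153 0.73 and Rpl38 0.29. The heat shock call was lost without control 3 (adjusted p = 0.225) or withdrawal 2 (0.201). The unfolded protein call was lost without control 1 (0.0579), control 3 (0.135) or withdrawal 2 (0.0696), and the ependymal call without control 2 (0.529) or withdrawal 2 (0.0696). In limma on log2(FPKM + 1) the heat shock, unfolded protein and ependymal lists missed the threshold (adjusted p = 0.0805, 0.0805 and 0.119).

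The remaining 28 tested lists did not pass, with camera adjusted p from 0.0615 for oligodendrocyte and myelin markers to 0.892 for choroid plexus markers and for dorsal and lateral medial habenula markers. Among other cell type lists the adjusted p was 0.314 for lateral habenula, 0.158 for meningeal fibroblast, 0.198 for GABAergic neuron, 0.317 for astrocyte, 0.374 for microglia and 0.443 for endothelial and pericyte markers. Among signalling lists it was 0.383 for nicotinic chaperones, 0.316 for muscarinic, 0.686 for ionotropic and 0.158 for metabotropic glutamate, 0.620 for GABA and 0.594 for neuropeptide receptors. For pacemaker channels, high-voltage calcium channels, vesicle release and cyclic AMP it was 0.686, 0.345, 0.496 and 0.836. For oxidative phosphorylation, the mitochondrial genome, glycolysis, the proteasome and sex-linked genes it was 0.620, 0.620, 0.686, 0.686 and 0.892. Gpr17, a receptor of committed oligodendrocyte precursors, fell from 95.2 ± 7.70 to 56.8 ± 6.76 CPM (log2 change -0.75, edgeR adjusted p = 0.0261), while its list of 7 precursor markers had a camera adjusted p of 0.0638. The sign of the median differed from that of the test for GABA receptors (median -0.07, tested higher), cyclic AMP signalling (0.11, tested lower) and choroid plexus markers (-0.22, tested higher). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had log2 changes between -0.03 and 0.03, and Ddx3y was present in all 10 libraries at 107 to 154 CPM.

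**Figure D3:**
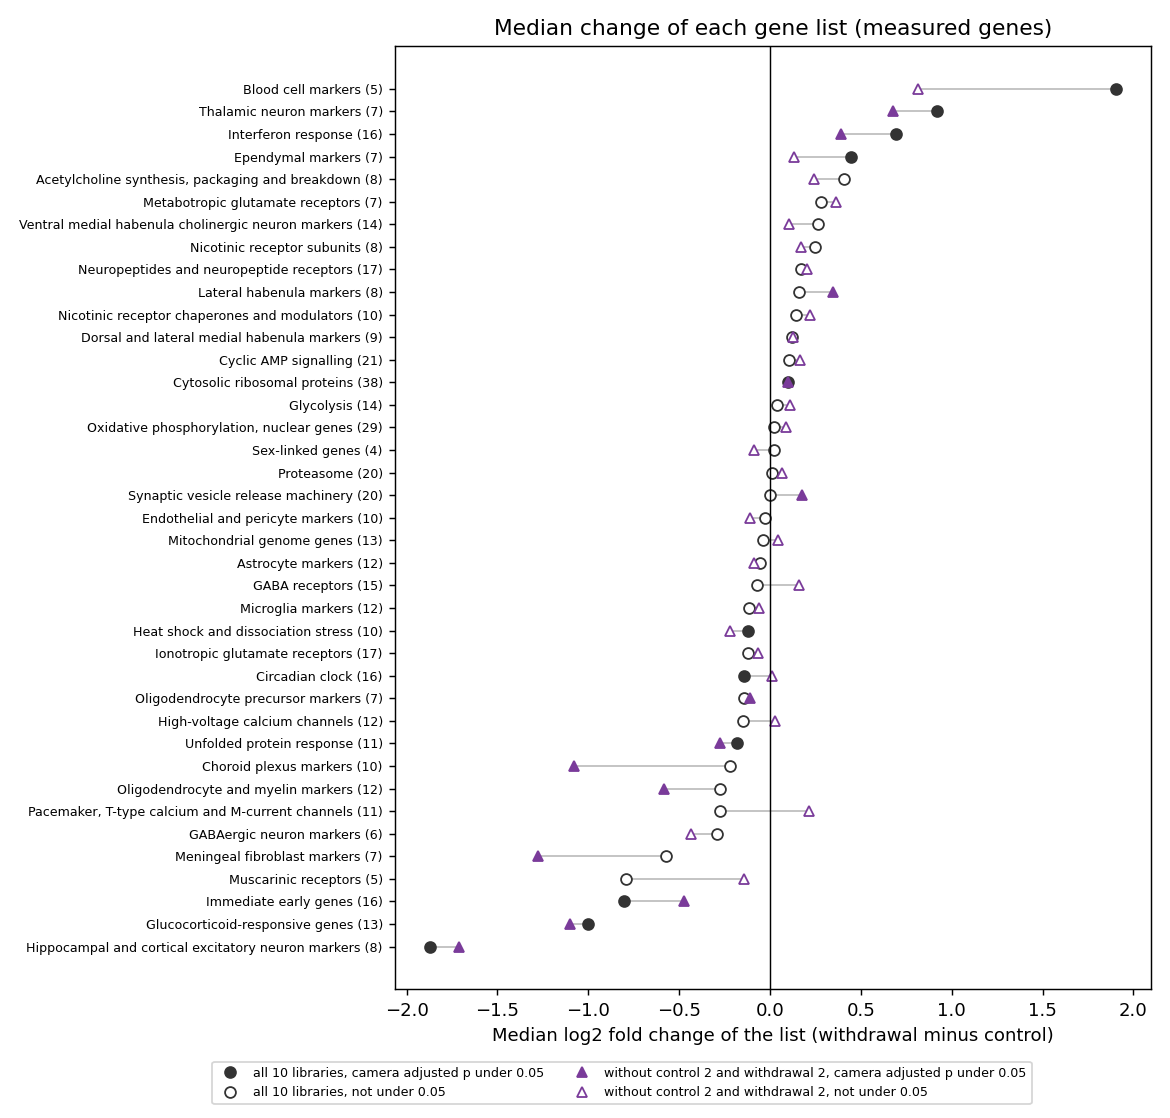
Median log2 fold change (withdrawal minus control) of each of the 39 tested gene lists, with the number of measured genes in brackets, over all 10 libraries (circles) and without control 2 and withdrawal 2 (triangles); filled symbols passed the camera threshold. Glucocorticoid-responsive genes passed in both, with medians of -1.004 and -1.10.

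In the 8 libraries whose habenula transcripts were abundant (3 controls and 5 withdrawal mice, chosen after the data were seen), all 31 genes were called again in the same direction, and all 13 glucocorticoid-responsive genes fell. Fkbp5 had a log2 change of -1.67 (SE 0.0703, edgeR adjusted p = 1.14e-05), Sgk1 -2.02 (edgeR adjusted p = 9.00e-04), Zbtb16 -2.62 (edgeR adjusted p = 5.11e-04) and Plin4 -3.17 (edgeR adjusted p = 3.03e-04). Chrna4, the nicotinic subunit that pairs with Chrnb2, rose by 0.65 on the log2 scale (SE 0.130, edgeR adjusted p = 0.0133). The acetylcholinesterase gene Ache rose by 0.51 (edgeR adjusted p = 0.02003) and Slc17a6 by 0.78 (edgeR adjusted p = 0.0213), while the choline transporter-like gene Slc44a1 fell by 0.45 (edgeR adjusted p = 0.00512). Tissue content was not separated from these 4 changes. Chrna4, Ache and Slc17a6 were highest in withdrawal 1, 3 and 5, which held the highest lateral habenula scores (7.13, 7.10 and 7.08). Ache was highest in withdrawal 1 and 5, which held the highest thalamic scores (5.70 and 6.01). Across groups these scores did not always order the genes. Chrna4, Ache and Slc17a6 were higher in withdrawal 4 (lateral habenula score 6.87) than in control 1 (6.93). Ache was also higher in withdrawal 6 (thalamic score 4.26) than in control 4 (5.10). Slc44a1 ran in the order of the oligodendrocyte and myelin score over the 6 withdrawal libraries, from 106 CPM at 7.76 in withdrawal 6 to 188 CPM at 8.99 in withdrawal 2. Withdrawal 2 was not among the 8 libraries of this change. At a like score Slc44a1 was higher in a control, with 157 CPM at 8.53 in control 3 against 131 CPM at 8.50 in withdrawal 4. Chat had a log2 change of 0.24 and Chrnb4 0.28 (edgeR adjusted p = 0.288 and 0.286). In total 2088 genes changed, 949 higher and 1139 lower. The hippocampal and cortical list stayed lower in withdrawal with a median of -1.71 (camera adjusted p = 1.85e-04; adjusted p = 0.598 with an estimated correlation). With its score as a term 2 genes passed in edgeR, Fkbp5 and Tsc22d3, the latter named after its values were seen. The score separated the groups in these libraries (4.52 to 5.76 in controls, 3.10 to 3.73 in withdrawal), so a call lost with this term does not show hippocampal tissue as its source. Sgk1, for example, kept a log2 change of -2.31 (edgeR adjusted p = 0.409), and the 13 glucocorticoid-responsive genes had log2 changes between -2.31 and -0.60. The number of genes changed without control 2 and withdrawal 2 was 872 when control 3 was left out as well, and 1265, 1273 and 1099 when withdrawal 1, 3 and 5 were.

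Without control 2 and withdrawal 2, 13 lists passed, among them 5 cell type lists and 1 signalling list that had not passed over 10 libraries. Oligodendrocyte and myelin markers were lower with a median of -0.58 (camera adjusted p = 5.93e-06), 7 of 12 members falling in edgeR, such as Cldn11 (-0.84) and Mal (-0.81). Meningeal fibroblast markers had a median of -1.28 (camera adjusted p = 3.51e-04) with 2 of 7 falling, Slc6a13 (-1.65) and Col1a2 (-1.28). Choroid plexus markers had a median of -1.08 (camera adjusted p = 0.0138) with no member passing. Lateral habenula markers had a median of 0.35 (camera adjusted p = 0.0138) with 3 of 8 rising, Gap43 among them (1.01). The adjusted p of each of these 4 lists was 0.667 with an estimated correlation. The glucocorticoid, hippocampal, interferon, immediate early, ribosomal, thalamic and unfolded protein lists passed again, and 2 more passed newly, but with an estimated correlation only the glucocorticoid list passed. Oligodendrocyte precursor markers were lower, with a median of -0.11 and 3 of 7 members falling (camera adjusted p = 0.00485), and vesicle release genes were higher, with a median of 0.17, 5 of 20 members rising and Cplx2 falling (camera adjusted p = 0.0496; adjusted p = 0.667 for both with an estimated correlation). The clock, blood, ependymal and heat shock lists did not pass in these 8 libraries (camera adjusted p = 0.2001, 0.0751, 0.277 and 0.122).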

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

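The tests of clock phase, of heat shock and of the 3 explanations for the near-absent habenula transcripts were chosen only after the result was seen. A library was set apart where its gap to the nearest other library of its group, over the group's range, passed Dixon's 95% critical value. Of 138 groups of values tested this way, 42 passed, against 6.9 expected by chance. Control 2 gave 20 of them, withdrawal 2 gave 21 and control 3 gave 1.

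Among list scores (mean log2 CPM), control 2 and withdrawal 2 lay lowest for ventral medial habenula markers (1.65 and 1.85), dorsal and lateral medial habenula markers (3.57 and 2.90), acetylcholine genes (1.59 and 2.72) and nicotinic receptor subunits (2.69 and 2.17). Among genes (log2 CPM), control 2 and withdrawal 2 lay lowest for Chat (-1.87 and -1.69), Slc18a3 (-1.87 and -1.29), Slc5a7 (0.57 and 2.02), Tac2 (0.77 and 0.55), Pou4f1 (-1.38 and 0.33), Chrna3 (2.27 and 1.11), Chrnb4 (-1.19 and 1.04) and Slc17a6 (2.44 and 6.43). Withdrawal 2 also lay lowest for Tac1 (0.90), Chrna4 (4.49) and Chrnb2 (6.11).

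For the near-absence of habenula transcripts in these 2 libraries, low depth is argued against by their totals, 20276566 counts or more against a median of 17411382 in the other 8. A loss of neurons in general is argued against by the synaptic vesicle score, which lay at -0.58 (withdrawal 2) and 0.44 (control 2) from the median of the other 8. In withdrawal 2 this score was the lowest of the 10 libraries (7.65, with 8.01 in control 4 next), so a partial loss of neurons there is not argued against. That score covers neurons of many kinds, so it does not speak to a loss of habenula neurons alone. A candidate explanation is tissue taken mostly from outside the habenula. The ventral habenula score lay at least 4.24 log2 units below the lowest of the other 8. It holds the transcripts whose near-absence raised the question, so it restates the pattern and adds no support. Transcripts of other neurons were high, with Neurod6 at 345 CPM in control 2 and Gad1 at 406 CPM in control 2 and 516 CPM in withdrawal 2. A sort for cholinergic neurons, which the source label names, would have removed such cells. In all 10 libraries the oligodendrocyte and myelin score was 7.76 or more and the astrocyte score 7.40 or more. The ventral habenula score was at most 6.57. These values argue against a pure sort of cholinergic neurons in any of the 10 libraries. A wrong label from outside the series was not tested, and no biological explanation was tested, since each group held 1 such library.

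Other list scores set control 2 apart as the highest for clock genes (6.42) and glycolysis (8.40) and as the lowest for meningeal (1.91), ependymal (-0.58) and choroid plexus markers (1.70) and sex-linked genes (5.77). Withdrawal 2 lay highest for hippocampal and cortical markers (5.22) and glucocorticoid-responsive genes (5.18), and lowest for glycolysis (8.10). Control 3 lay highest for the unfolded protein response (6.01). Among genes, control 2 lay lowest for Fabp7 (3.18) and highest for Mertk (6.31), and withdrawal 2 lay highest for Fkbp5 (5.39), Mertk (5.05) and Ddit4 (5.02).

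The lower glucocorticoid-responsive genes in withdrawal (score difference -1.16) were weighed against hippocampal tissue, oligodendrocyte tissue and clock phase. With the hippocampal marker score as a term the difference was -0.96 (95% interval -1.39 to -0.52), and with the oligodendrocyte and myelin score -1.07 (-1.37 to -0.78), which argue against either tissue as the whole cause. The clock output genes minus Arntl and Npas2 differed by -0.43 (-0.79 to -0.07) in the 8 other libraries, a size under the 0.5 set for a phase shift with an interval reaching beyond it, so a difference in clock phase cannot be told apart from the treatment. Lower glucocorticoid signalling in withdrawn mice, and differences in handling or time of collection, stay open as untested hypotheses.

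The lower immediate early genes in withdrawal (score difference -0.85, 95% interval -1.73 to 0.04) were weighed against hippocampal tissue and dissociation stress. With the hippocampal score as a term the difference was 0.22 (-0.26 to 0.69), and the slope on that score was 0.59 (0.40 to 0.78), in line with hippocampal tissue in the controls as the source. In the 8 other libraries the difference went from -0.68 (-1.17 to -0.20) to -0.08 (-1.08 to 0.92) with that term, but the slope of 0.39 (-0.19 to 0.97) had an interval that included 0, so these libraries alone do not settle it. The heat shock score was lower in withdrawal by a difference of -0.31 (-0.51 to -0.12), which leaves dissociation stress open and cannot be told apart from the groups. Lower neuronal activity in withdrawal stays open as untested.

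In the splits of the 10 libraries into 4 and 6, 2 of 100 gave as many changed genes as the real split (31), the other with 177, and 2 of 100 gave as many higher genes (5; highest other 164). That other split set control 2 and withdrawal 1, 3 and 5 against the rest and points to a structure of the samples. For lower genes 1 of 100 did (26; highest other 13). For these 3 counts the share of the 100 drawn splits was under 0.05. Chance is not excluded for the 11 lists, which 51 of 100 splits matched (highest other 20). In the 8 libraries, chosen after the data were seen, 1 of 56 splits, the smallest share possible, gave as many changed genes (2088). The highest other was 493, for withdrawal 1, 3 and 5 against the rest. As many lists (13) came from 24 of 56 splits (highest other 17), so chance is not excluded for them. The hippocampal score separated the groups in these 8 libraries, so the split counts do not tell treatment from tissue content.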

How the results depend on the processing

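The results of DESeq2, limma on log2(FPKM + 1), filterByExpr and of leaving out control 2 and withdrawal 2, with its own alternatives, were chosen only after the result was seen. The main comparison gave 31 genes changed in withdrawal, 5 genes higher in withdrawal, 26 genes lower in withdrawal and 11 lists. In that order the counts were 10, 1, 9 and 7 in limma on log2(FPKM + 0.1) and again on log2(FPKM + 0.5), 12, 1, 11 and 7 on log2(FPKM + 1), and 16, 2, 14 and 7 on the TPM scale. Quantile normalization gave 28 genes (25.0% higher against 16.1%) and 7 lists, and no filter beyond a mean FPKM above 0 gave 2 higher genes of 21. Array weights gave 1732, 846 and 886 genes (48.8% higher), DESeq2 381, 150 and 231, and the 8 libraries without control 2 and withdrawal 2 gave 2088, 949 and 1139. A 2-fold threshold left 15, 2 and 13, and with an unadjusted p 431, 97 and 334. Camera with an estimated correlation and fry each passed 1 list. Median-of-ratios factors (32), robust moderation (30), filterByExpr (26) and a mean FPKM of at least 5 (22) stayed within 1.5 times. All 31 genes kept their direction in every one of these settings in which they were tested (23 of them at the FPKM minimum of 5), and 31, 31 and 10 of them were called by DESeq2, array weights and limma on log2(FPKM + 1). Leaving out 1 library gave 4 to 893 changed, 0 to 340 higher and 4 to 553 lower genes and 9 to 16 lists, with 893 without withdrawal 2. The count of higher genes was 0 in edgeR without control 3 or 4 or withdrawal 1, 3, 4, 5 or 6, where 1578 to 2760 genes had an unadjusted p under 0.05. The cause was not tested, except that a stricter threshold removes genes by construction. With the replicate block, edgeR called 0 changed, 0 higher and 0 lower genes (1914 at an unadjusted p under 0.05) and 11 lists. The same-numbered libraries deviated with correlations of 0.03, 0.31, -0.13 and 0.28. Of the 8 libraries numbered 1 to 4, 5 correlated best with their own number in the other group. The main comparison was unpaired because the labels do not say that the numbers pair mice. These values do not exclude a pairing, under which no gene was called. Withdrawal 5 and 6 had no control of the same number. Under the block Chrna3 was -0.22, Tac1 -0.37, Tac2 -0.029 and the list: Nicotinic receptor subunits -0.0023. The number of genes changed without control 2 and withdrawal 2 (2088) was 951 with the block, 2 with the hippocampal marker score as a covariate, 872 to 2911 without 1 more library and 1952 to 2899 by other tools and scalings. Directions reversed as follows. The list: Choroid plexus markers (-0.22) was 0.31, 0.23 and 0.12 in limma on log2(FPKM + 0.1), + 0.5 and + 1, 0.25 on the TPM scale, and -0.67 to 0.080 without 1 library. The list: Circadian clock (-0.14) was 0.0081 with array weights, 0.013 without control 2 and withdrawal 2, and -0.21 to 0.0015 without 1 library, and Chrna5 (-1.59) was 0.10, 0.24 and -1.92 to 0.073. Without 1 library the ranges were -0.15 to 0.58 for the list: Ventral medial habenula cholinergic neuron markers, -0.016 to 0.48 for nicotinic subunits, -0.021 to 0.68 for Chat, -0.16 to 0.55 for Chrna3, -0.15 to 0.58 for Pou4f1, -0.14 to 0.60 for Slc5a7, -0.12 to 0.49 for Tac1 and -0.16 to 0.57 for Tac2. The glucocorticoid, interferon, hippocampal and ribosomal lists passed in all 22 other settings with the preset correlation. The next counts cover all genes and lists followed across settings, including those above. The settings that left out no single library kept direction and side of the threshold in 1068 gene and 180 list values. They lost the call in 78 and 29, gained it in 94 and 12 and reversed direction in 5 and 7. Leaving out 1 library did so, in that order, in 881 and 167, 142 and 8, 30 and 10, and 7 and 5. The simulated comparison over these 10 libraries recovered 11.9% of 1.5-fold changes, so most changes of that size would be missed in it. Without control 2 and withdrawal 2 the simulated recovery was 62.7%.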

Other observations

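Genes of neurotransmission outside the acetylcholine and nicotinic lists changed in both directions in the 8 libraries without control 2 and withdrawal 2, an alternative chosen only after the result was seen. Chrm1, a muscarinic receptor of cortical and hippocampal neurons, fell by 2.48 on the log2 scale (edgeR adjusted p = 0.00515) and the T-type calcium channel gene Cacna1h fell by 2.52 (edgeR adjusted p = 0.00120). The adenylyl cyclase gene Adcy1 fell by 2.62 (edgeR adjusted p = 0.00120) and the vesicle protein gene Cplx2 fell by 1.28 (edgeR adjusted p = 0.00682). The glutamate receptor genes Grin2d, Grik1 and Grm4 rose by 1.09, 0.89 and 0.95, the GABA receptor genes Gabrg3 and Gabra3 by 0.71 and 0.93, the T-type channel gene Cacna1g by 0.71 and the sodium leak channel gene Nalcn by 0.31 (edgeR adjusted p from 0.00813 for Nalcn to 0.0330 for Gabra3). Grin2a and Gabra5 had log2 changes of -1.21 and -1.16 (edgeR adjusted p = 0.00803 and 0.0211). Grin2d, Grik1, Grm4, Gabrg3, Gabra3 and Cacna1g were highest, among the 8, in withdrawal 1 and 5, which also held the highest thalamic marker scores (5.70 and 6.01), so thalamic content was not separated from these rises. Chrm1, Cacna1h, Adcy1, Cplx2, Grin2a and Gabra5 were highest in control 2 and, among the 8, in control 3, which held the highest hippocampal marker scores (7.24 and 5.76 in that order), so hippocampal content was not separated from these falls. None of these 13 genes passed over all 10 libraries. The muscarinic, ionotropic and metabotropic glutamate, GABA receptor, pacemaker channel and cyclic AMP lists did not pass in the 8 libraries (camera adjusted p from 0.107 to 0.872).

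Clock genes moved in both directions in the 8 libraries. Nr1d1 and Arntl, chosen after their values were seen, rose by 0.69 and 0.54 on the log2 scale (edgeR adjusted p = 9.00e-04 and 0.00845), while Per1, Per2 and Per3 had log2 changes of -0.51, -1.21 and -0.52 (edgeR adjusted p = 0.00559, 3.31e-04 and 0.00151). Cry1 and Tef fell with the period genes, by 0.43 and 0.22 (edgeR adjusted p = 0.0141 and 0.0157), and the other 9 of the 16 listed clock genes did not pass. Tph1, an enzyme of the pineal gland, reached 35.2 CPM in withdrawal 3 and 3.92 CPM in withdrawal 6, and was under 1 CPM in the other 8 libraries. No pineal list member passed the filter on mean FPKM. Leaving out other pairs of 1 control and 1 withdrawal library gave at most 989 changed genes (control 1 and withdrawal 2), against 2088 without control 2 and withdrawal 2.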
